A study of Homo sapiens with 12 samples.

How the data were processed

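Total RNA from 12 cultures was partly hydrolysed with alkali, fragments of 20 to 40 nt were ligated to linkers with a modified tRNA ligase and the libraries were sequenced on the Ion Proton, per the labels' protocols. The titles number the replicates of each group from 1 to 3 and call them biological. The submitters' processing notes name cutadapt 2.0, Bowtie2 2.3.4.1 and the build hg38 without saying what each was used for. The deposited tables hold, per the file headers, whole-number counts of read 5' ends and read 3' ends at each of 8164 positions of 10 RNAs, for every replicate separately. They also hold the authors' score per position and replicate, a fraction between 0 and 1. From the deposited values it was found that this score is 1 minus the sum of both kinds of ends at the position over the mean of the weighted means of the 6 positions on each side, with weights from 1.0 down to 0.5, set to 0 where negative. The formula gave the deposited score at 8044 positions in all 12 libraries to within 5e-10. The authors' overview gives the mean fraction per group and site. In 13 of these means, in WT or the knockout only, single replicates had been replaced by deposited recalculated values, which raised for example the WT mean of 18S-Cm462 from 0.536 to 0.870. Because the recalculation was uneven between groups, the scores used here are those from both kinds of ends, except at 8 sites in positions 1 and 2 of U1, U2, U4 and U5, where the deposited recalculated value was used in all groups. All 28 recalculated values outside these 8 sites equalled a score from read 5' ends alone to within 0.0001. At the 8 sites, 87 of 96 values equalled a score from read 5' ends and downstream neighbours, and the largest difference was 0.0291.

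Sites are named by RNA, base and position in the sequence of the deposited tables. No genomic coordinates are given because no genome was used here, and guide RNAs are named only where the deposited overview lists them, which it does for snRNA sites. The score is a ratio of counts and not a share of methylated molecules, so no binomial interval is given. The mean number of read ends at the neighbours of an rRNA site had a median between 1251 and 3056 in WT and knockout libraries and between 172 and 890 in the siRNA libraries, and between 24.1 and 269 at snRNA sites. Reads without molecular identifiers are not independent molecules, so such numbers bound only the counting error. Replicate libraries of a group differed by more than sampling noise (chi-square per degree of freedom from 7.46 to 301), and their site scores correlated with an r from 0.847 to 0.931.

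Scores were fitted with limma 3.58.1 in R 4.3.3 on the linear scale, with 4 group means over the 12 libraries, two-sided tests and Benjamini-Hochberg adjustment over 141 sites at 0.05. The contrasts were knockout minus WT, siDHX15 minus siNT, the difference of these effects, and siNT minus WT. Lists of sites were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The lists were each RNA, each base, 3 classes of mean score, the parts of 28S before and after its middle, and snRNA sites by listed guide. Sites were named by a rule, namely up to 20 per main comparison that passed the threshold with all 3 treated scores on one side of all 3 control scores, by size of the difference. Up to 10 more that passed in both comparisons, the 5 largest differences of effects, the 5 smallest p-values where fewer than 5 sites passed, and 2 to 4 list members as examples were added. These choices and the first set of alternatives were made before the data were examined. The latter were other fits (only the groups compared, a replicate block, leaving out each library of the groups compared, robust and trended variance, edgeR 4.0.16 quasi-likelihood on counts with the neighbour mean as offset), other scores (logit, centred libraries, 2 neighbours, listed neighbours left out, score computed from the counts) and filters (a neighbour mean of 100, a mean score of 0.2, a difference of 0.05). Read 5' or 3' ends alone, no floor, thinning to 875096 read ends, the overview's scores, recalculated values wherever given, both ends at the sites with a 3' end score, classes of level by the control libraries alone, leaving out libraries of the groups not compared, and the library index as a block were chosen after seeing the data. So were all alternatives for siNT minus WT and for unlisted positions, and those for the overlap other than the threshold of 0.1, 2 neighbours, a difference of 0.05, the replicate block and leaving out each library.

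Same-numbered siNT and siDHX15 replicates deviated together from their group means, with correlations across sites of 0.117, 0.160 and 0.166. These values were not tested, so a pairing of the samples by number is not established. The file headers name a library index for each library. The 6 indices were used once in each of the 2 experiments, and each index therefore links 1 library of WT or knockout to 1 of siNT or siDHX15. The fits were tested in 20 simulations in which 40 of the 141 sites were lowered, drawn from those with high control scores. Normal noise with the replicate spread of the real libraries was added to the scores, and counting noise was added to that spread. The noise was independent between sites, so deviations shared by the sites of a library were not simulated. For the knockout comparison limma recovered 43.5% of decreases of 0.1, 76.5% of 0.2 and 96% of 0.4, with 0.65 false calls on average, and edgeR 15%, 42.5% and 61.5%, with 0.3. For siDHX15 it recovered 45.5%, 73.5% and 90.5%, with 1.4 false calls, and edgeR 17%, 44% and 58%, with 0.3.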

Results

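RiboMeth-seq was used to measure 2'-O-methylation of ribosomal and small nuclear RNA in HEK293 Flp-In T-REx cells, a human embryonic kidney line with an integration site for inducible transgenes. Partial alkaline hydrolysis cuts RNA less often at the bond that follows a 2'-O-methylated nucleotide, so a methylated position has few read ends compared with its neighbours. The RMS score expresses this depletion as a fraction, from 0 for no depletion to 1 for no read ends at the position. The 12 libraries fell into 4 groups of 3 replicates, which were wild-type cells (WT), GPATCH4 knockout cells, and wild-type cells given non-target siRNA (siNT) or siRNA against DHX15 (siDHX15). DHX15 is an RNA helicase of the DEAH-box family and GPATCH4 carries a G-patch, a motif through which proteins bind such helicases. A score was given for 141 sites, 41 in 18S rRNA, 68 in 28S rRNA, 2 in the shortest rRNA of the tables (154 nt) and 30 in the snRNAs U1, U2, U4, U5 and U6. Replicates 1 to 3 held 16314082, 8677305 and 13288018 read ends in WT, and 16236537, 8218990 and 7437847 in the knockout. The siRNA libraries were shallower, with 1796931, 1736931 and 1705278 read ends in siNT and 875096, 1462423 and 5111963 in siDHX15. Neither the GPATCH4 nor the DHX15 transcript is measured by this assay, so the knockout and the knockdown were not checked here.

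The first comparison asked which methylation sites depend on GPATCH4. In the knockout, 35 of the 141 sites had lower scores than in WT and 1 had a higher score (limma, Benjamini-Hochberg adjusted p under 0.05). At 18S-Gm509 the score fell from 0.902 ± 0.0121 (SD, n = 3) to 0 in every knockout replicate (adjusted p = 1.48e-09), where the neighbouring positions held 523 to 1137 read ends on average in the knockout libraries. Scores of 0 in every knockout replicate were also found at 18S-Cm797, where WT had 0.824 ± 0.0585, and at 18S-Cm174, where WT had 0.658 ± 0.0163. Negative scores are set to 0, so at these sites and at 18S-Gm509 the spread between knockout replicates is not seen. The SE and p-values there contain no spread from the knockout and may be too small. With no floor, a setting chosen after the data were seen, 34 of the 35 lower sites were still called. Near-complete losses were measured at 18S-Um799, from 0.945 ± 0.00954 to 0.126 ± 0.162, at 28S-Cm2803, from 0.883 ± 0.0417 to 0.117 ± 0.0371, and at 18S-Um1804, from 0.732 ± 0.0293 to 0.038 ± 0.0655.

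Partial losses made up most of the remaining calls. The score of 28S-Am3760 fell from 0.980 ± 0.00529 to 0.480 ± 0.0373, a difference of -0.499 (SE 0.0189, adjusted p = 1.89e-08). At 28S-Cm3869 it fell from 0.851 to 0.309 and at 18S-Gm644 from 0.928 to 0.315. At 18S-Am668 it fell from 0.917 to 0.243, and at 28S-Gm4494 from 0.932 to 0.310. The knockout replicates were widely spread at 18S-Am166, where the score fell from 0.907 ± 0.0173 to 0.345 ± 0.301, and at 18S-Am99, where it fell from 0.904 ± 0.0422 to 0.314 ± 0.227. Without GPATCH4 KO replicate 2 the difference at 18S-Am166 was -0.389, against -0.562. The call there was lost when the fit held the WT and knockout libraries alone (adjusted p = 0.0526). Over all 35 lower sites the median difference was -0.331, and the 3 knockout scores lay below the 3 WT scores at each of them. Chance alone separates 3 values from 3 at 10% of sites, and 38.3% of the 141 sites were separated.

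By RNA, 17 of the 41 sites in 18S, 15 of the 68 in 28S and 1 of the 2 in the rRNA of 154 nt were lower. The last was Gm75 of that RNA, which fell from 0.945 ± 0.00916 to 0.773 ± 0.0132. In the snRNAs 2 of 30 sites were lower, U2-Um47, from 0.934 ± 0.00575 to 0.738 ± 0.0474, and U4-Am65, a site with SCARNA5 as its listed guide, from 0.898 ± 0.0599 to 0.695 ± 0.0782. The call at U4-Am65 was lost without WT replicate 1 (adjusted p = 0.0514), WT replicate 2 (0.0710) or GPATCH4 KO replicate 2 (0.0572), in edgeR (0.152), on the logit scale (0.171), from read 5' ends alone (0.107) and with the libraries thinned to the shallowest (0.366). Its neighbouring positions held only 7.59 to 42.8 read ends on average in the knockout libraries, and the site 19 in total. No site of U1, U5 or U6 passed the threshold in limma. Lower calls were found among all the bases, at 12 of 44 Am, 8 of 32 Cm, 9 of 39 Gm and 6 of 26 Um sites. By mean score over all 12 libraries, 4 of 46 sites at 0.9 or more, 27 of 82 between 0.5 and 0.9 and 4 of 13 below 0.5 were lower. A loss lowers that mean and so moves a site to a lower class. Classed afterwards by the 6 WT and siNT libraries alone, the numbers were 20 of 68, 15 of 65 and 0 of 8. In 28S, 5 of 22 sites before the middle of the sequence and 10 of 46 after it were lower. Of the snRNA sites with a listed guide, 1 of 7 whose guide also serves another listed site, 0 of 3 with more than 1 guide and 1 of 12 with 1 guide were lower. Adjusted over the list alone, 1 site of 18S became a higher call, and lower calls numbered 14 in 28S, 3 at 0.9 or more and 28 between 0.5 and 0.9, with no other list changed.

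No list of sites passed a test against the other sites, adjusted over the 20 lists. The 18S sites came closest (camera, adjusted p = 0.0744, and adjusted p = 0.321 with an estimated correlation), and from read 5' ends alone they passed it (adjusted p = 0.0256, and adjusted p = 0.117 with an estimated correlation). Taken by themselves, 13 of the 20 lists moved down on balance (fry, adjusted p under 0.05), among them 18S (8.37e-08) and 28S (0.000114), every base and every class of mean score. The lists not past the threshold in fry were U1, U4, U5, U6, the first part of 28S and the snRNA sites with 1 guide or more than 1. Median and mean differences had opposite signs for 28S (0.00171 and -0.0600), its first part (0.00687 and -0.0316), Cm (0.00477 and -0.0936), U1 (-0.0157 and 0.0122), U5 (0.00558 and -0.0152), U6 (0.0167 and -0.0164) and sites with more than 1 guide (0.0226 and -0.00169). For 28S and Cm the camera direction, relative to the other sites, was up and the fry direction was down.

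The only higher call was 28S-Am400, at 0.666 ± 0.0418 in WT and 0.795 ± 0.0340 in the knockout (adjusted p = 0.0368). It was not past the threshold from read 5' ends alone, with a difference of 0.0353, nor in edgeR (adjusted p = 0.0569). It was also lost without WT replicate 1 (adjusted p = 0.133), WT replicate 2 (0.0750), GPATCH4 KO replicate 2 (0.118), GPATCH4 KO replicate 3 (0.0666) or siNT replicate 2 (0.0511), with the replicate block (0.0662), on the logit scale (0.0703), with robust and trended variance (0.0696) and from read 3' ends alone (0.110).

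With each library centred on its median deviation, 33 sites were lower and 13 were higher in the knockout. With the library index as a block, a term chosen after the data were seen, 29 sites were lower and 0 higher in limma, of which 27 were among the 35. Of the sites named here, 18S-Am166, 18S-Am576, 28S-Gm1316, 28S-Am2814, 28S-Am2400, U4-Am65 and the rise at 28S-Am400 were not past the threshold with that block (adjusted p = 0.0783, 0.136, 0.180, 0.489, 0.120, 0.0752 and 0.602). Their differences were, in this order, -0.518, -0.403, -0.245, -0.0407, -0.301, -0.278 and 0.0484 with the block, which left 3 residual degrees of freedom, against -0.562, -0.489, -0.296, -0.0463, -0.293, -0.203 and 0.129 without it. The call at 28S-Gm1316 was also lost from read 5' ends alone (-0.321, adjusted p = 0.0627).

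**Figure D1:**
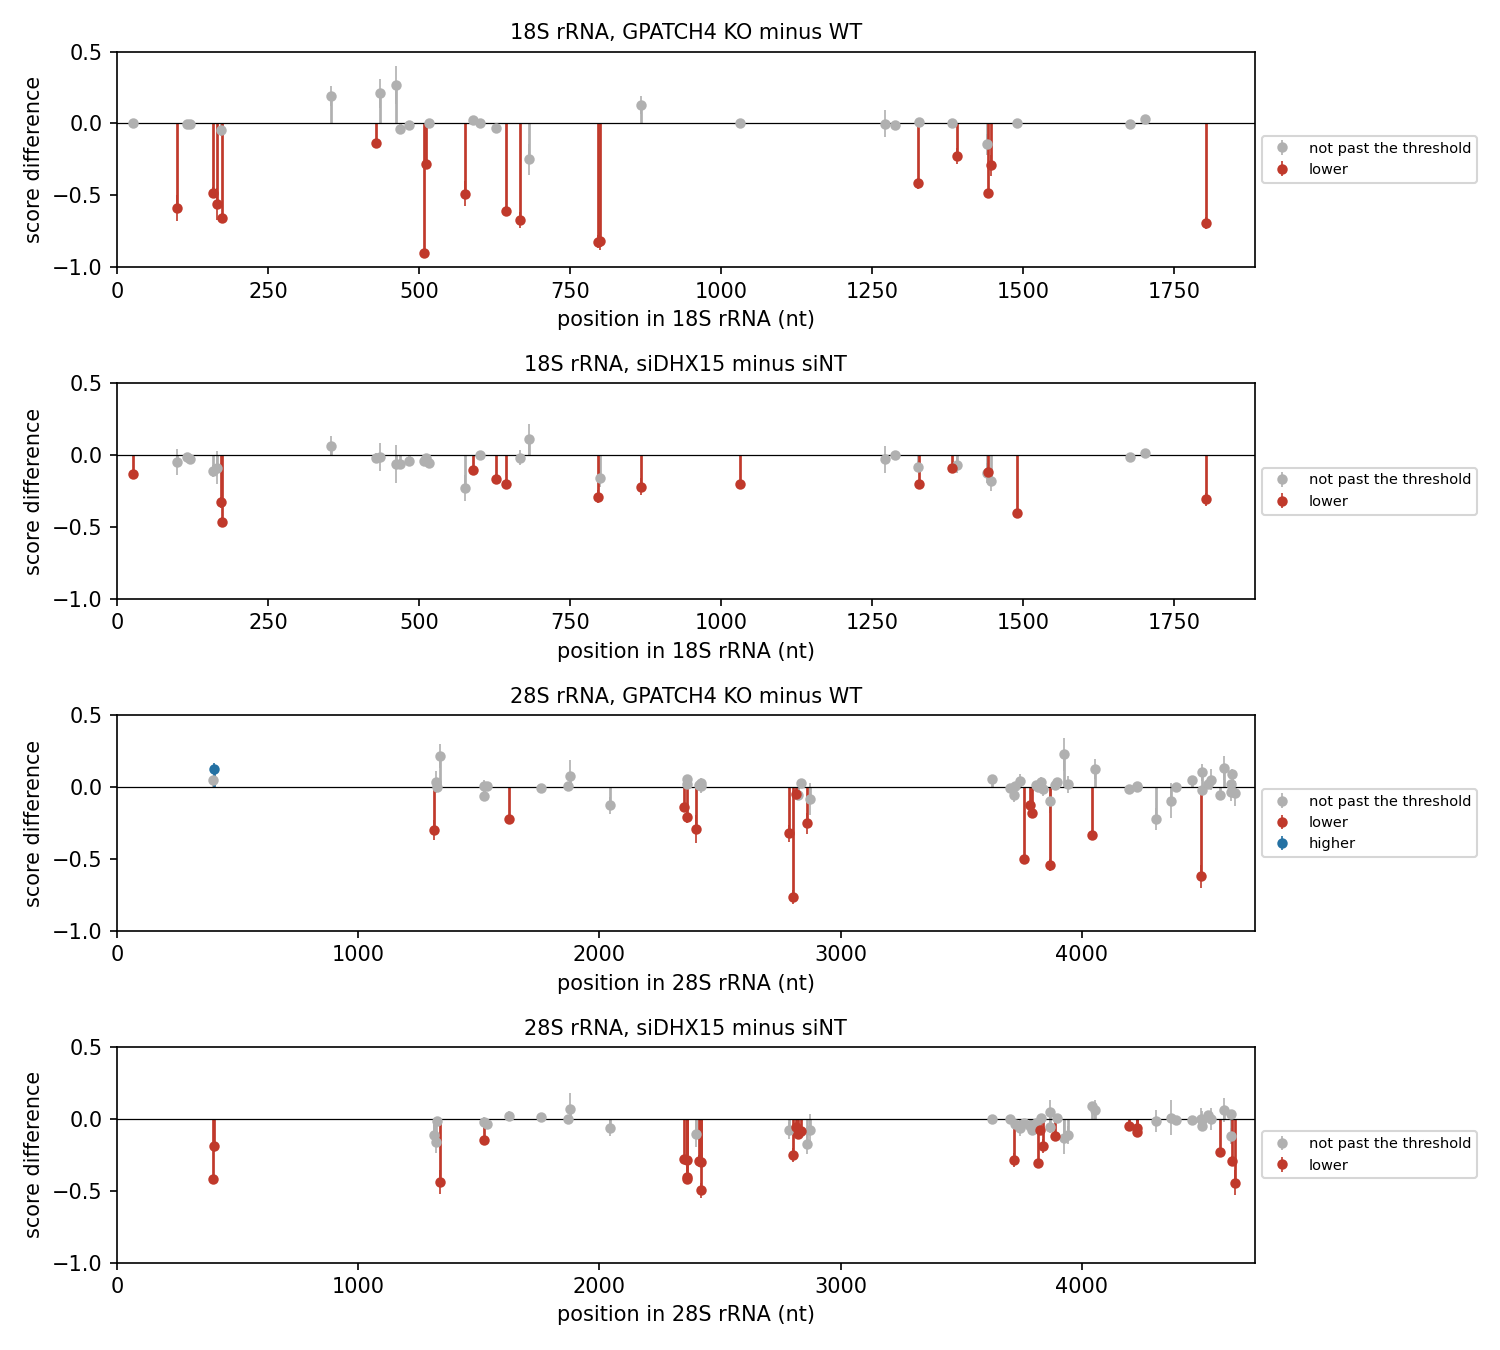
Score differences (vertical axes, fraction) by position in nucleotides along 18S and 28S rRNA for GPATCH4 KO minus WT and siDHX15 minus siNT, with SE bars from the limma fit and calls at an adjusted p under 0.05 in colour. The knockout has 17 lower calls in 18S and 15 in 28S, and siDHX15 has 14 in 18S and 26 in 28S.

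The second comparison asked which sites depend on DHX15. In siDHX15, 44 of the 141 sites had lower scores than in siNT and 0 had a higher score (limma, adjusted p under 0.05). An unadjusted p under 0.05 was found at 59 sites, and edgeR called 48 lower and 0 higher. The largest decrease was at 28S-Cm2421, from 0.874 ± 0.0317 (SD, n = 3) to 0.378 ± 0.133 (adjusted p = 4.77e-05). At 28S-Am398 the score fell from 0.889 ± 0.0388 to 0.470 ± 0.0267 and at 28S-Am2362 from 0.928 ± 0.0304 to 0.513 ± 0.0488. At 18S-Gm1490 it fell from 0.949 ± 0.00349 to 0.548 ± 0.0598. The median difference over the 44 lower sites was -0.225, and all siDHX15 scores lay below all siNT scores at each of them.

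Of the sites in 28S, 26 of 68 were lower, and 14 of 41 in 18S. Neither of the 2 sites in the rRNA of 154 nt passed the threshold. A stretch of 28S from position 2350 to 2423 held 8 listed sites, of which 7 were lower, namely Cm2350, Am2362, Gm2363, Cm2364, Um2414, Cm2421 and Gm2423. Am2400 lay between them and did not pass the threshold (-0.103, adjusted p = 0.486). Its score was lower in the knockout (-0.293, adjusted p = 0.0480), where the replicates were at 0.594, 0.186 and 0.606, and without GPATCH4 KO replicate 2 the difference was -0.155 (adjusted p = 0.0182). The call was lost with only the WT and knockout libraries in the fit (0.174), without WT replicate 1 (0.0800), 2 (0.129) or 3 (0.114), siNT replicate 1 (0.0657), 2 (0.0701) or 3 (0.0698) or siDHX15 replicate 1 (0.0681), 2 (0.0574) or 3 (0.0567), and from read 3' ends alone (0.130). The sites of this stretch were singled out after their values were seen. In the first part of 28S, before the middle of the sequence, 11 of 22 sites were lower, against 15 of 46 after it. No list passed a test against the other sites, and the first part of 28S came closest (camera, adjusted p = 0.266, and adjusted p = 0.480 with an estimated correlation). Taken by themselves, 15 of the 20 lists moved down on balance (fry, adjusted p under 0.05). That test takes in the median difference of -0.0569 over all 141 sites and was not run on centred libraries. The lists also share sites, so their number does not count separate findings. Of the other 28S and 18S sites, 28S-Gm4637 fell from 0.680 ± 0.0859 to 0.237 ± 0.111 (from read 3' ends alone -0.393, adjusted p = 0.208, not past the threshold), 18S-Um172 from 0.867 ± 0.0187 to 0.539 ± 0.0169 and 28S-Um3818 from 0.812 ± 0.00553 to 0.502 ± 0.0706. At 28S-Cm1340 the score fell from 0.664 ± 0.147 to 0.227 ± 0.0796, a call lost with the library index as a block (adjusted p = 0.0975).

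In the snRNAs 4 of 30 sites were lower, 3 in U2 and 1 in U6. U2-Gm19 fell from 0.774 ± 0.0794 to 0.468 ± 0.120 (adjusted p = 0.00197). U2-Am30, which has the same listed guide, SCARNA9, fell from 0.952 ± 0.0101 to 0.905 ± 0.0248 (adjusted p = 0.0476), and U2-Am1 from 0.988 to 0.933. U2-Am30 and U2-Am1 were chosen after their values were seen, and with each library centred their differences were 0.0220 and 0.0140. The call at U2-Am30 was lost with the replicate block (adjusted p = 0.0708) and without siNT replicate 1 (0.127), 2 (0.0639) or 3 (0.128) or siDHX15 replicate 1 (0.109) or 3 (0.0588). It was also lost without WT replicate 1 (0.0720), 2 (0.0768) or 3 (0.0674) or GPATCH4 KO replicate 1 (0.0632) or 3 (0.0547), in edgeR (0.0561) and from read 5' (0.0841) or 3' ends alone (0.765). The call at U2-Am1 was lost without siNT replicate 1 (0.0584) or 2 (0.0545), and its siNT score rests on 1 read end at the site in total, with 28.3 to 46.8 on average at its neighbours. The U6 site was Am70, at 0.691 ± 0.151 in siNT and 0.426 ± 0.130 in siDHX15 (adjusted p = 0.0289). Its call was lost without siNT replicate 2 (adjusted p = 0.0585), siNT replicate 3 (0.10), siDHX15 replicate 1 (0.0600) or siDHX15 replicate 2 (0.0963), with each library centred (0.0979) and in edgeR (0.0940), and from read 3' ends alone the difference was -0.0140. Each of the 4 bases had lower sites, with 15 of 44 Am, 10 of 32 Cm, 11 of 39 Gm and 8 of 26 Um. By the mean over all 12 libraries, which the losses themselves lower, 12 of 46 sites at 0.9 or more were lower, 31 of 82 between 0.5 and 0.9, and 1 of 13 below 0.5. By the 6 control libraries alone they were 23 of 68, 21 of 65 and 0 of 8. No site of U1, U4 or U5 passed the threshold in limma. In the siNT libraries the neighbours of the U4 sites held only 2.81 to 7 read ends on average. At U1 and U5 sites they held as few as 8.44 and 9.27, so losses in these RNAs could have been missed. Of the snRNA sites with a listed guide, 2 of 7 whose guide also serves another listed site, 0 of 3 with more than 1 guide and 2 of 12 with 1 guide were lower. Adjusted over the list alone, lower calls numbered 0 in U6, 11 at 0.9 or more, 1 of the 7 and 1 of the 12, with no other list changed. The median and mean differences of U5 had opposite signs (-0.0186 and 0.00433).

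The median difference over all 141 sites was -0.0569 in siDHX15 and -0.00607 in the knockout. With each library centred, 27 sites were lower and 15 higher in siDHX15, so the direction of part of the calls is relative to this shift. With the library index as a block, 31 sites were lower and 0 higher in limma, of which 28 were among the 44. Of the sites named here or by the naming rule, 28S-Cm1340, 18S-Um1442, 28S-Am2814, 28S-Am3718, 18S-Gm867, U6-Am70, U2-Am30 and U2-Am1 were not past the threshold with that block (adjusted p = 0.0975, 0.423, 0.216, 0.0588, 0.0669, 0.126, 0.438 and 0.194). Their differences were, in this order, -0.315, -0.0407, -0.0564, -0.227, -0.301, -0.253, -0.0377 and -0.0646 with the block and -0.437, -0.114, -0.0557, -0.288, -0.219, -0.264, -0.0472 and -0.0551 without it. The call at 18S-Gm867 was also lost without siNT replicate 1 (adjusted p = 0.0774) or 2 (0.0668) or siDHX15 replicate 2 (0.0736), with each library centred (0.0930) and from read 5' ends alone (0.309). The mean score at 18S-Gm867 was 0.547 in siDHX15 and 0.766 in siNT, but 0.541 in WT, so siDHX15 was not below untreated cells there. From read 3' ends alone, over the 128 sites they could score, 20 sites were lower.

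**Figure D2:**
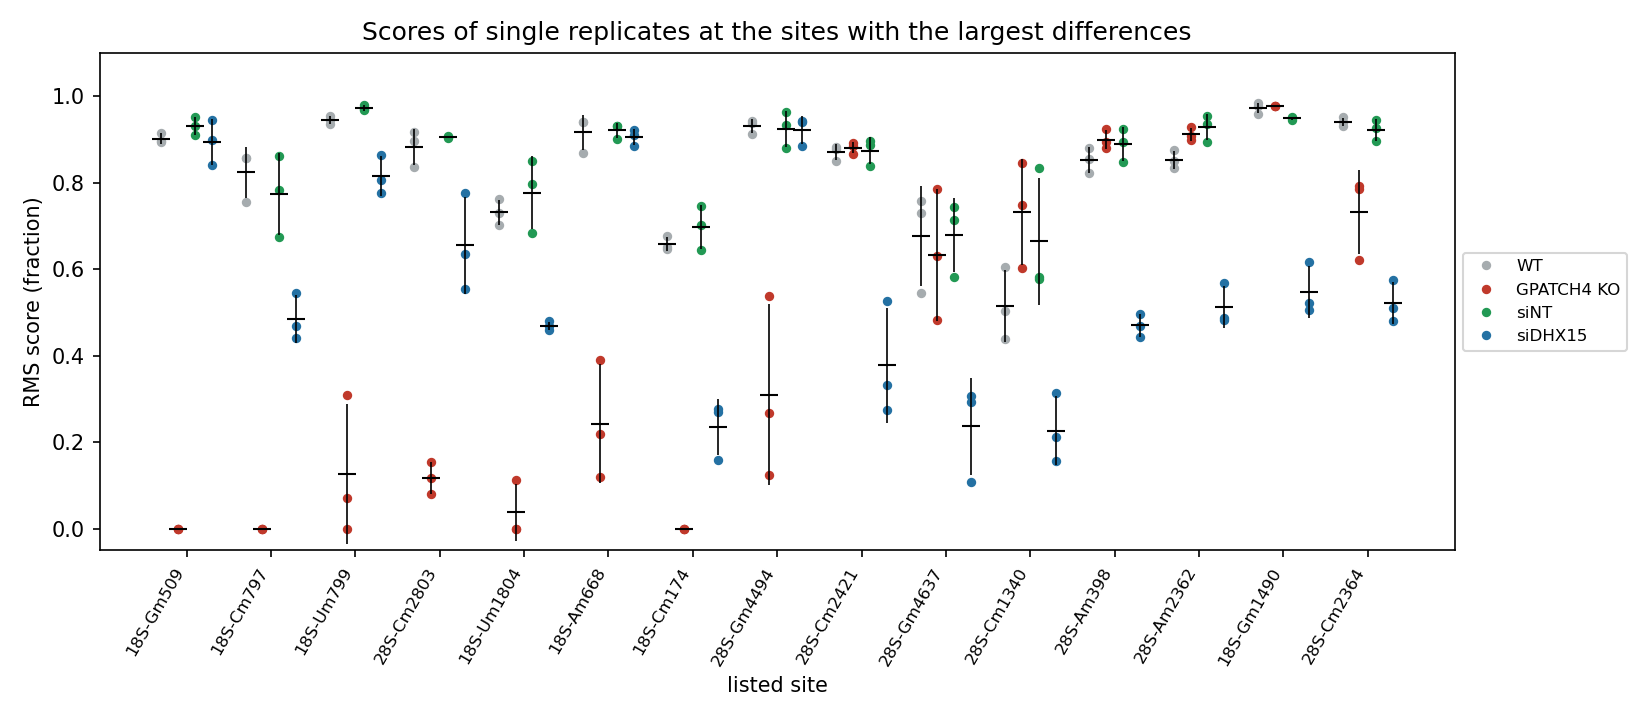
RMS scores (vertical axis, fraction) of single replicates at the sites with the largest differences in either comparison, as points by group, with black dashes and bars for the mean and SD. All knockout replicates are at 0 at 18S-Gm509, 18S-Cm797 and 18S-Cm174, and the siDHX15 replicates lie below the siNT replicates at 28S-Cm2421. Negative scores are set to 0.

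The title of the series sets DHX15-dependent against DHX15-independent sites, so the lower calls of the 2 comparisons were set side by side. They shared 9 sites, namely 18S-Cm174, 18S-Gm644, 18S-Cm797, 18S-Um1442, 18S-Um1804, 28S-Cm2350, 28S-Cm2364, 28S-Cm2803 and 28S-Am2814. Independent lists of the same sizes would share 10.9 sites, and the test did not separate the overlap from that number (Fisher's exact test, two-sided, p = 0.529, odds ratio 0.704 with a 95% interval of 0.261 to 1.76). Without GPATCH4 KO replicate 2 the number of shared sites was 17, against 12.9 for independent lists (Fisher's exact test, p = 0.110). The call at 18S-Um1442 in siDHX15 was lost without siNT replicate 3 (adjusted p = 0.0678) or siDHX15 replicate 3 (0.0581), and when the libraries were thinned (0.288). With each library centred its difference was -0.0452 (adjusted p = 0.339), and with 2 neighbours a side -0.0990 (0.133). The knockout call at 28S-Am2814 was lost without WT replicate 1 (0.0728), 2 (0.0872) or 3 (0.132) or GPATCH4 KO replicate 1 (0.126) or 3 (0.101) or siNT replicate 1 (0.0518), 2 (0.0646) or 3 (0.0527), and its siDHX15 call without siNT replicate 2 (0.0522) or 3 (0.0507). From read 3' ends alone the siDHX15 calls at 18S-Cm797, 18S-Um1442, 18S-Um1804, 28S-Cm2803 and 28S-Am2814 were lost (0.0782, 0.0782, 0.0512, 0.227 and 0.208). Their differences were -0.338, -0.148, -0.236, -0.182 and -0.0897 from these ends, against -0.289, -0.114, -0.308, -0.251 and -0.0557 from both. The knockout calls at 28S-Cm2364 (-0.262 against -0.208, adjusted p = 0.105) and 28S-Am2814 (-0.0220 against -0.0463, adjusted p = 0.864) were lost likewise. The siDHX15 call at 18S-Cm797 was also lost with no floor at 0 (0.121, at the same difference of -0.289) and that at 18S-Um1804 on the logit scale (0.0740). Across the 141 sites the differences had a Pearson r of 0.0961 (permutation p = 0.258, adjusted 0.29) and a Spearman rho of 0.0892 (permutation p = 0.29, adjusted 0.29), where sites are not independent replicates.

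The difference between the 2 effects was tested for every site, and 53 sites passed, 24 with the more negative effect in the knockout and 29 with the more negative effect in siDHX15. With each library centred the numbers were 25 and 19, and in edgeR 14 and 23. With the library index as a block 43 sites passed, among them 20 of the 24 and 18 of the 29. The largest was at 18S-Gm509, where the difference of effects was -0.865 (SE 0.0344, adjusted p = 6e-08), with siNT at 0.932 ± 0.0208 and siDHX15 at 0.894 ± 0.0526. The knockout replicates, all at the floor of the score, add no spread to that SE. The knockout effect was also the more negative at 18S-Um799 (difference of effects -0.661), 18S-Am668 (-0.657) and 28S-Gm4494 (-0.619). From read 3' ends alone the differences at 18S-Um799 and 28S-Gm4494 were not past the threshold (adjusted p = 0.0943 and 0.0532). The opposite held at 28S-Cm1340, with a difference of effects of 0.655 (SE 0.119, adjusted p = 0.00142). Part of this value is a higher score in the knockout, 0.733 against a WT mean of 0.516. In the authors' overview, with 2 WT replicates recalculated, the WT mean was 0.699, so the size of the difference depends on the WT score used. Of the 26 sites lower in the knockout and not past the threshold in siDHX15, 18 passed the test of the difference, and 8 did not. Of the 34 sites lower in siDHX15 and not past the threshold in the knockout, 25 passed it and 9 did not. These tests set a knockout against an siRNA treatment whose remaining DHX15 was not measured. A smaller effect in siDHX15 therefore does not show that a site is independent of DHX15. 28S-Am400 was the 1 site higher in the knockout and lower in siDHX15, and from read 3' ends alone it was not past the threshold in siDHX15 (-0.152, adjusted p = 0.109). Among the 9 shared sites, 6 had a larger loss of score in the knockout and 2, 28S-Cm2350 and 28S-Cm2364, in siDHX15. The difference at 28S-Cm2364 was lost without any 1 of the WT replicates, GPATCH4 KO replicates 1 and 2, siNT replicates 1 and 3 and siDHX15 replicates 2 and 3 (adjusted p from 0.0570 to 0.0734). With the library index as a block the differences at 28S-Cm2350, 28S-Cm2364 and 18S-Cm174 were not past the threshold (0.0520, 0.105 and 0.0711). In edgeR those at 18S-Gm644, 18S-Um1804, 28S-Cm2803, 28S-Cm2350 and 28S-Cm2364 were not (0.641, 0.20, 0.0970, 0.115 and 0.443). On the logit scale the difference at 18S-Gm644 was not past the threshold either (adjusted p = 0.248). In simulations edgeR recovered fewer decreases than limma (42.5% against 76.5% of decreases of 0.2 in the knockout comparison). In the real libraries, however, edgeR called 38 sites lower in the knockout and 48 in siDHX15, against 35 and 44 in limma. Differences of scores are compared in limma, and fold changes of read ends relative to the neighbours in edgeR. A larger loss of score need not be a larger fold change, so which effect is the larger can depend on the scale. How far scale or power accounts for the lost differences was not tested. At 28S-Am2814 the effects differed by 0.00942 (adjusted p = 0.787). Its 2 calls were small, at -0.0463 and -0.0557, and with each library centred neither was past the threshold (-0.0176 and 0.0135, adjusted p = 0.423 and 0.565). Both were also lost with only the 2 groups compared in the fit (adjusted p = 0.0782 and 0.0566), and the knockout call with 2 neighbours a side (0.128). The difference at 18S-Cm174 was -0.196, and 0.0119 from read 5' ends alone. It was also not past the threshold with 2 neighbours a side (-0.169, adjusted p = 0.118) or with thinned libraries (-0.178, adjusted p = 0.141). From read 3' ends alone the differences of effects at 18S-Cm797 and 18S-Um1804 were -0.472 and -0.291, not past the threshold (adjusted p = 0.0762 and 0.0737).

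**Figure D3:**
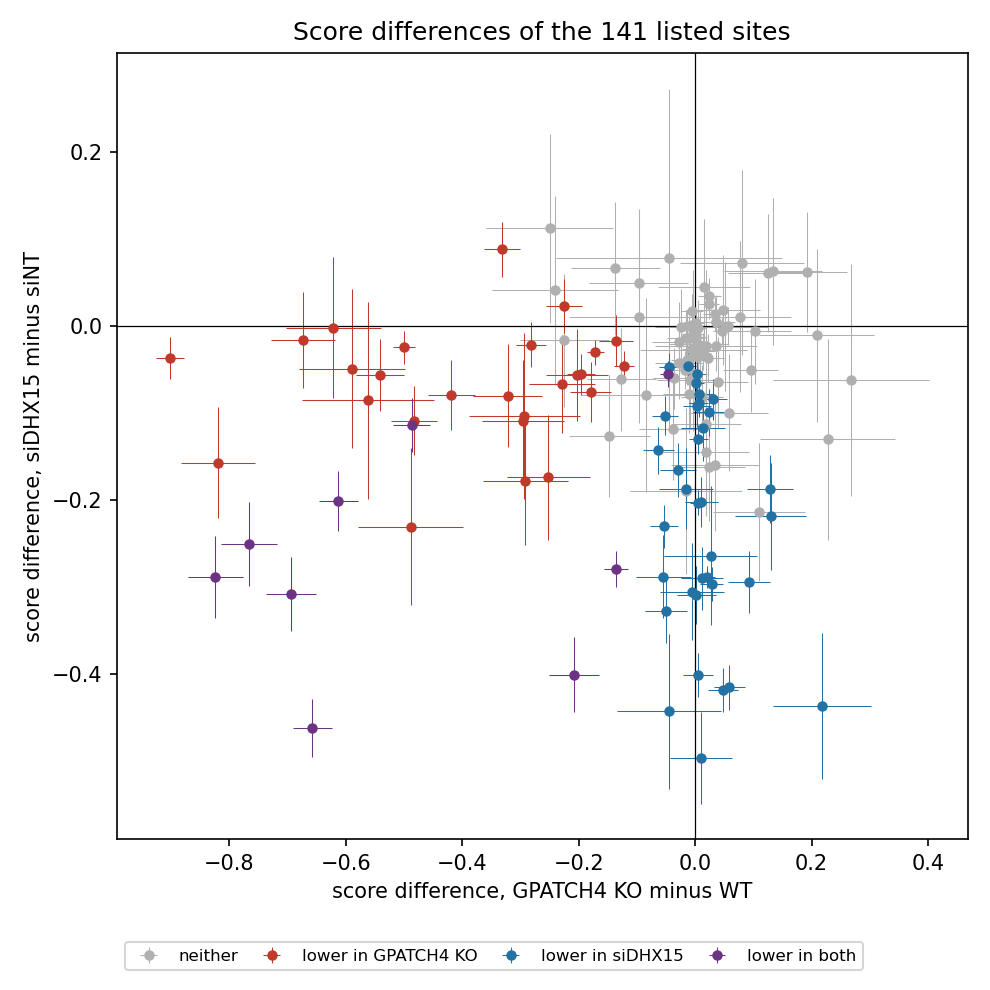
Score difference in siDHX15 (vertical axis) against that in GPATCH4 KO (horizontal axis), both as fractions with SE bars, for the 141 listed sites coloured by their lower calls. The 9 sites lower in both lie below and to the left of 0, and the Pearson r over all sites is 0.0961.

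The 2 kinds of control were compared as background. Between siNT and WT no site passed the threshold in limma or in edgeR, and 10 of the 141 sites had an unadjusted p under 0.05. The smallest p-values belonged to 28S-Gm3627 (0.813 in WT and 0.909 in siNT), 28S-Gm4623 (0.703 and 0.853), 18S-Gm867 (0.541 and 0.766), U4-Am1 (0.838 and 1) and 28S-Am2362 (0.853 and 0.928), with adjusted p-values from 0.144 to 0.370. The siNT score of U4-Am1 carries little information, since the site held 0 read ends in siNT and its neighbours only 2.87 to 4.47 on average. At 3 counts over the lowest of these, the limit that a count of 0 allows is a share of 1.05, so that library by itself excludes no level. No limit was computed for the siNT libraries together. At 6740 unlisted positions of the same RNAs no position passed the threshold in either main comparison (limma), and 272 in the knockout and 270 in siDHX15 had an unadjusted p under 0.05. The median SD between replicates was 0.201 at these positions and 0.0474 at listed sites. In simulated data only 36% of changes of 0.6 at unlisted positions were recovered in the knockout comparison and 40% in siDHX15, so changes of that size could have been missed there. Between siNT and WT 1 unlisted position was lower and 625 had an unadjusted p under 0.05. No unlisted position had a score of 0.75 or more in all 12 libraries.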

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

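The tests chosen after seeing the data are those with read 5' or 3' ends alone, no floor, thinning, the overview's or recalculated scores, both ends at the sites with a 3' end score and the index block, classes of level by the control libraries, libraries of the groups not compared left out, all for siNT against WT and unlisted positions, and those of the shared sites other than with a threshold of 0.1, 2 neighbours, a difference of 0.05, the replicate block or a library left out. Without each library in turn, calls numbered from 31 to 38 in the knockout comparison, from 37 to 53 in siDHX15, from 43 to 52 for the difference of effects, from 0 to 1 for siNT against WT (1 without GPATCH4 KO replicate 3, siDHX15 replicate 2 or siDHX15 replicate 3; the cause was not tested), and the shared lower sites from 7 to 17. The highest for siDHX15 and for the shared sites came without GPATCH4 KO replicate 2, and with libraries of its own groups alone left out siDHX15 had at most 44. With the replicate block the knockout had 33 calls, siDHX15 46, the difference of effects 50 and siNT against WT 0, and the shared sites numbered 8. This block held a single effect per replicate number, shared by all groups, so a pairing of siNT with siDHX15 was not fitted by itself. The block left 43 of the 44 lower siDHX15 sites called, all but U2-Am30. Among the named sites it ended the knockout calls at 28S-Am400 (adjusted p = 0.0662), 28S-Am2814 (0.0537) and 28S-Am2400 (0.0537). Same-numbered WT and knockout libraries had correlations of 0.120, 0.0459 and -0.000863, and 2 of the 3 knockout libraries correlated best with their own number. Read 3' ends alone gave 20 calls in siDHX15, 26 for the difference of effects and 4 shared sites. The same 128 sites scored from both ends gave 42 and 52 calls, so the number of sites is not the cause, which was not otherwise tested. The shared sites were 16 at a threshold of 0.1, 15 on the logit scale and 17 with edgeR; the cause was not tested. For siNT against WT, 2 sites passed with only those groups in the fit and 2 from read 5' ends alone, and the cause was not tested. Among named sites past the threshold in the main fit or in the alternative, the sign turned at 28S-Am2814 in siDHX15 with centred libraries (0.0135), 28S-Gm3627 (0.0689), U2-Am30 (0.0220) and U2-Am1 (0.0140) in siDHX15 likewise, at U5-Am1 in the knockout with the index block (-0.142), and at 18S-Cm174 for the difference of effects from read 5' ends alone (0.0119). Centring moves all siDHX15 differences by the same amount, so small losses at other sites, not past the threshold, turn with it too. Unlisted positions had 0 calls in either comparison in limma with the replicate block, only the groups compared, robust variance or a neighbour mean of 100. At named sites that passed the threshold, 831 values under an alternative stayed past it in the knockout and 59 did not, 822 and 62 in siDHX15, and 1095 and 132 for the difference of effects, apart from those whose sign turned. The siRNA libraries were the shallower ones, and thinning every library left 34 calls in the knockout comparison and 44 in siDHX15.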

Other observations

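The tests of depth, of random placement in 28S, of cleavage along the stretch in 28S and of shared library indices were chosen after the results were seen, and so were the alternatives for the index and for single kinds of read ends. U3 and U8, small nucleolar RNAs that take part in rRNA processing, are in the tables but hold no listed site. Of 124 scored positions of U8, 21 had an unadjusted p under 0.05 in siDHX15 against siNT and 4 in the knockout against WT. For U3 the numbers were 19 and 11 of 205 positions. None passed the adjustment over unlisted positions, with smallest adjusted p-values of 0.296 in U8 and 0.306 in U3 for siDHX15, and neighbouring positions share read ends. The unlisted position with the highest minimum over all 12 libraries was C628 of 28S, at 0.683, and U1248 of 18S came to 0.646.

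Libraries of the 2 experiments that carried the same index deviated from their group means in the same direction. The correlations across sites ran from 0.161 to 0.496 over the 6 same-index pairs, with a mean of 0.321. Of the 720 matchings of indices only the real one gave as high a mean (exact one-sided p = 0.00139, the smallest that 720 matchings can give). This is consistent with an effect of the index on site scores, as a hypothesis found and tested on the same libraries. Of the indices, 2 were carried only by knockout and siDHX15 libraries and 2 only by WT and siNT libraries, so such an effect could enter both comparisons.

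The lower calls were set against 3 technical explanations. With the index as a block, the median difference at the 35 lower sites of the knockout was 1.22 times that without it. At the 44 lower sites of siDHX15 it was 0.989 times. No index occurred in both groups of either comparison, so index and treatment cannot be separated within an experiment. The blocked differences come from links across the experiments and hold only if an index adds the same amount in each. On that untested condition the values argue against the index as the whole cause of the lower calls. The block also left only 3 residual degrees of freedom. Thinning every library to the same depth left 32 of the 35 and 40 of the 44 sites called. The score is a ratio within a library, and thinning leaves it unchanged on average. The kept calls therefore show only that most of them outlast the added counting noise. Thinning cannot test other properties of a shallow library, so it does not decide on depth as a cause. Centring each library left 33 of the 35 knockout sites called, against a shift common to all sites, but 27 of the 44 in siDHX15, between the bounds set in advance, so that for siDHX15 a common shift may account for part of the calls and a broad effect of the knockdown stays open too. Of the 10 splits of the 6 libraries, 1 gave as many calls as the real 36 in the knockout comparison and 1 as many as the real 44 in siDHX15, in both cases the real split, with 0 as the highest of the others, those that part every same-numbered siNT and siDHX15 pair included, but 10 splits are too few for a share under 0.05.

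Other splits were counted for the remaining results as well. For the difference of effects, 1 of 100 splits, the real split, gave as many as the real 53 sites, the highest of the others being 29. These splits relabelled the libraries of both comparisons, so they bear on the absence of any effect. They cannot show whether the 2 effects differ from each other. For siNT against WT, where the real count is 0 and the highest other 0, and for unlisted positions, where the real count is 0 and the highest others are 6 for the knockout and 2 for siDHX15, all 10 splits gave as many. Any split reaches a real count of 0, so this outcome was fixed in advance and decides nothing.

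The 7 lower sites of siDHX15 between positions 2350 and 2423 of 28S were a pattern noticed in the data. Leaving listed sites out of the neighbour windows kept their median difference at -0.290, against -0.296, so its size hardly depended on listed neighbours. A loss at a listed neighbour raises the neighbour mean and with it the score of the site beside it. Overlapping windows could therefore not create joint losses, and this test could not have spoken for them. A change by the same factor along the stretch cancels in the score of any position, listed or unlisted, whose neighbours lie in it. Of the neighbours of the unlisted positions 96.4% do, so the median difference of -0.00929 at these positions decides nothing. An uneven change would move single positions either way. The median absolute difference at the 66 unlisted positions, scored without the floor at 0, was 0.0775 (95% bootstrap interval 0.0549 to 0.114), closer to 0 than the bound of -0.148. Of 4777 other 28S windows of the same length, 87.2% had as high a value, with a median of 0.102. This argues against an uneven change of that size at most unlisted positions of the stretch. A change by the same factor cancels at listed sites whose neighbours lie in the stretch, so it cannot account for lower scores there. For the listed sites at its ends, and for an even change of another kind, the values do not decide. Nor do they argue against a change at the listed positions alone. The number of neighbouring called pairs in 28S was 13, against 9.56 on average when calls were shuffled among its 68 sites (one-sided permutation p = 0.0634, adjusted 0.254 over 4 tests), so random placement of the calls remains open.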
